A study of Mus musculus with 6 samples.

How the data were processed

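The series holds 6 libraries of interscapular brown adipose tissue, 3 from mice kept in the cold and 3 from mice kept at normal housing temperature. Per the labels' protocols, frozen tissue was homogenised in a phenol reagent, RNA with a poly(A) tail was captured in 2 rounds on oligo(dT) beads, and 100 ng of it went into a barcoded Oxford Nanopore direct cDNA library, a protocol without PCR. The labels' extraction text speaks of another fat depot at the homogenisation step, while the tissue fields of all 6 samples name interscapular brown adipose tissue; the latter was followed here. Each library was run on 2 flow cells, and each run has its own table.

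The deposited tables hold whole-number counts of reads per annotated transcript, and list a transcript only where it had at least 1 read. The authors' read mapping used minimap2 on the genome build GRCm38, per the submitters' processing notes. The version of minimap2, the annotation release, the treatment of reads that fit several transcripts, the use of strand and any read filter are not given in the sources used here. A read that fits overlapping transcripts on both strands, or near-identical copies of a gene, can therefore have been counted on either. The deposited counts carry no normalization.

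Transcript identifiers were matched to the GENCODE M21 annotation of GRCm38, with the version suffix where possible and without it otherwise. Of 59543 transcripts with a read, 59278 matched with their version and 59371 in total. The 172 unmatched transcripts held 9857 of 11789059 reads (0.084%) and were left out of library sizes and tests. Counts were summed over the 2 flow cells of each mouse, so that n is the number of mice, and over the transcripts of each gene. The mouse numbers in the labels differ between the groups, so no mouse was paired with another.

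Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and the tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. Figures were drawn with matplotlib 3.10.9. Genes and transcripts were tested with edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) after TMM normalization and the filterByExpr filter, with all 6 libraries in the fit, no covariate, and Benjamini-Hochberg adjusted p-values called at 0.05. Adjusted p-values for single genes and transcripts are from this test unless another tool is named. The fold change SE is on the log2 scale. CPM are read counts scaled to a common library size, given as mean ± SD over the 3 mice of a group. Transcript usage was tested with edgeR's diffSpliceDGE in genes with at least 2 tested transcripts, with Simes p-values per gene, adjusted over genes.

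There were 28 gene lists written down before the data were examined, as were the tests, the alternatives and the rule for the genes named in the text. Each list with at least 3 tested members was tested with limma's camera on log2 CPM (prior count 2) with an inter-gene correlation preset at 0.01, adjusted over the lists. Camera with an estimated correlation, fry, and fry's mixed test were run beside it. Camera compares the members of a list with all other tested genes. Both fry tests ask only whether the members change. Because 6 of the names written down matched no annotated gene with a read in these libraries, they were left out. The lists cover the thermogenic programme, cAMP and immediate early response, de novo lipogenesis, triglyceride synthesis, lipolysis and lipid uptake, fatty acid oxidation, glycolysis and glucose uptake, glycogen metabolism, the tricarboxylic acid cycle, the nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, creatine and calcium cycling, the unfolded protein response, the proteasome, cytosolic ribosomal proteins, cold-shock and heat-shock proteins, the circadian clock, secreted factors of brown fat, cell division, and markers of white adipocytes, skeletal muscle, macrophages, lymphocytes, endothelium, fibroblasts and preadipocytes, pericytes and smooth muscle, Schwann cells and erythroid cells.

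Named genes followed a rule of 4 parts. The first part always named 10 genes of brown fat, from Ucp1 to Prdm16. The second named the 10 largest changes in each direction among called genes whose groups did not overlap and whose mean over the 6 libraries was at least 30 CPM. The third named up to 4 called members of each list by size of change, or the 2 with the largest change where none was called. The fourth named the genes called for transcript usage and a fixed set of genes with known alternative transcripts. The rule gave 110 genes, of which the text gives a part; a gene outside the rule is said to be so. All 118 genes and usage genes were compared with the transcripts of other genes by sequence with minimap2 2.31, and 13 shared at least 200 nt at 95% identity or more with another gene that had at least 20 reads.

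Library measures such as the share of mitochondrial reads were compared with exact two-sided permutation tests of 3 against 3 mice, which cannot give a p below 0.1, with Benjamini-Hochberg values over the 20 measures. Intervals of read ratios are exact 95% intervals, and they and the level that 3 reads represent cover counting error only.

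The scripts were tested on simulated data in 5 draws, made from the real means, the library sizes and edgeR's own estimates of spread. Each gene or transcript was drawn independently of the others. The recovered and false shares below therefore hold only where those estimates are right, and DESeq2's were larger for genes with few reads. For genes, 70% of 2-fold and 92.2% of 4-fold changes were recovered among 8459 tested genes, with a false share of calls of 6.3%. For transcripts, the recovered shares were 63.8% and 88.6% among 11178, with a false share of 7.4%. For usage, 23.6% of 2-fold and 75.6% of 4-fold changes of a transcript were recovered among 2430 genes, with a false share of 1.6%. Over 5 draws with no change, 6 genes were called. A shift of 0.5 on the log2 scale put into the tricarboxylic acid cycle list was recovered as a median of 0.52 (camera adjusted p = 8.13e-25). There 1 other list was called. The simulated genes were not correlated, while the estimated correlation of that list in the real data was 0.393.

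The alternatives were RLE size factors, DESeq2, limma voom, no filter, a filter at a mean of 10 CPM, mitochondrial genes left out, a length offset, edgeR's legacy quasi-likelihood fit, other usage tests, other list tests, each flow cell alone and each mouse left out in turn. Added after the data had been seen were a skeletal muscle covariate, for genes and for lists, and a fit on 4 libraries without cold mouse 15 and control mouse 2. The raw signal and the reads themselves were not analysed here. Results for a few genes and 1 gene family are not reported here.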

Results

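Poly(A) RNA of interscapular brown adipose tissue, the heat-producing fat depot between the shoulder blades, was sequenced as long cDNA reads from 6 male C57BL/6N mice of 20 weeks. The 3 cold mice had been housed alone at 4 °C for 24 h before the tissue was taken, and the 3 control mice had been kept at 22 to 24 °C. If the control mice were not housed alone, an effect of single housing cannot be told apart from that of the cold. Each mouse gave 1 direct cDNA library that was run on 2 flow cells, and reads were counted per annotated transcript. Summed over both flow cells, control mice 2, 9 and 14 had 1829442, 1989224 and 2238056 reads, and cold mice 4, 11 and 15 had 2082203, 1982292 and 1657985 reads. At these depths 3 reads correspond to between 1.34 and 1.81 CPM, and 15661 to 16418 genes had a read in each library.

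The groups separated before any test. The first principal component of the 500 most variable genes held 70.4% of the variance and parted all 3 cold mice from all 3 control mice. Libraries of the same group differed by more than sampling noise, with chi-square values per degree of freedom of 2.09 to 3.42, and libraries of different groups differed more, by 10.9 to 18.84. The 2 flow cells of a mouse also differed by more than sampling noise. Over all genes they gave 5.8 to 7.64, more than different mice of the same group. Mitochondrial reads took 23 to 27.9% of the reads on flow cell 1 and 34.1 to 39.3% on flow cell 2, and without mitochondrial genes the chi-square per degree of freedom was 2.33 to 2.9. Over 5342 genes measured on both flow cells, log2 fold changes from 1 flow cell alone correlated with those from the other at a Pearson r of 0.812 and a Spearman rho of 0.69.

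The comparison of gene counts asked which genes differed in this tissue after a day in the cold. Ckb, the brain-type creatine kinase, rose 25.8-fold in the cold, from 24.9 ± 7.13 to 652 ± 138 CPM (SD, n = 3). Elovl3, an elongase of very long chain fatty acids, rose 5.83-fold, and Dio2, which makes active thyroid hormone, rose 4.99-fold. Genes for making fatty acids went the other way, among them Acly, the ATP citrate lyase, which was 7.35-fold lower, and Acaca, an acetyl-CoA carboxylase, which was 3.86-fold lower. Of 8684 tested genes, 847 were higher and 848 were lower in the cold (19.5%), of which 221 and 193 changed more than 2-fold. The groups did not overlap in 3051 genes (35.1%), against 10% by chance. DESeq2 called 467 higher and 353 lower genes, and flow cell 2 alone gave 429 and 408. With a skeletal muscle covariate, 616 genes were higher and 561 lower, and without cold mouse 15 and control mouse 2, 569 were higher and 506 lower.

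**Figure D1:**
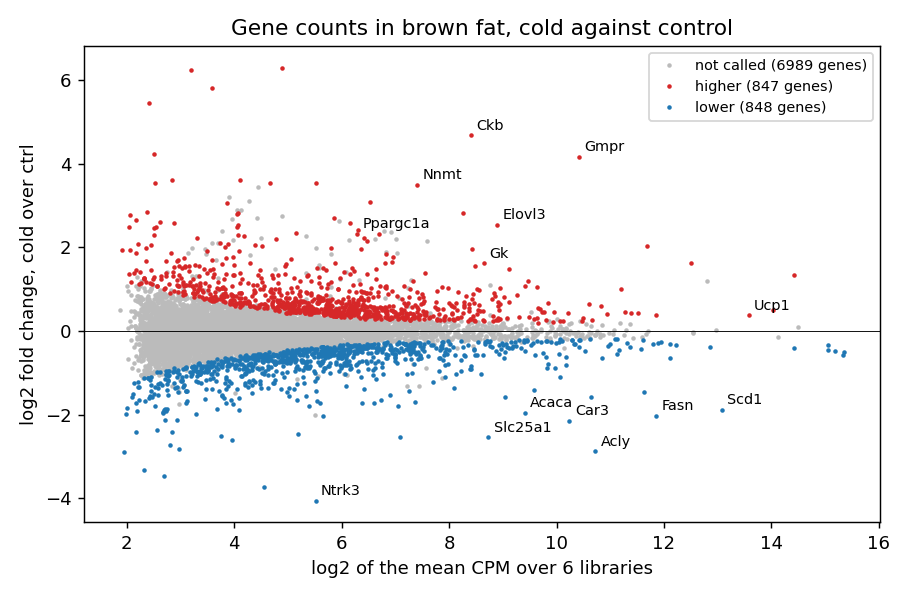
Log2 fold change in the cold (vertical axis) against the log2 mean CPM over 6 libraries (horizontal axis) for each tested gene, with 847 higher genes in red and 848 lower genes in blue. Ckb and Gmpr lie above 4 on the log2 scale and Ntrk3 below -4, while Ucp1, already among the most abundant genes, rose by 0.37.

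Ucp1, the uncoupling protein that lets mitochondria release energy as heat (chromosome 8, 83290352 to 83298452), was already abundant in control mice and rose 1.29-fold, from 10670 ± 840 to 13810 ± 125 CPM (n = 3, adjusted p = 0.000144). Much larger changes were seen in genes that act around it. Ppargc1a, a coactivator that drives the making of mitochondria (chromosome 5, 51454250 to 51567726), rose 5.02-fold, from 25.6 ± 3.97 to 130 ± 6.02 CPM (adjusted p = 1.2e-11). Dio2 (chromosome 12, 90724552 to 90738438) rose from 34.5 ± 9.73 to 174 ± 15.1 CPM (adjusted p = 4.01e-09), and Elovl3 (chromosome 19, 46131897 to 46135694) from 139 ± 14.3 to 810 ± 191 CPM (adjusted p = 0.000475). Gk, which phosphorylates glycerol (chromosome X, 85701937 to 85776819), was 3.09-fold higher, at 197 ± 62 against 607 ± 49.3 CPM (adjusted p = 0.0178). Its adjusted p was 0.0715, 0.073 and 0.0691 without cold mouse 11, control mouse 14 and cold mouse 15, and ranged from 8.1e-10 to 0.075 over all alternatives. Pdk4, a kinase that shuts off pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309), rose 1.59-fold (adjusted p = 0.00504), a call that the fit on 4 libraries lost (adjusted p = 0.0551; alternatives up to that value).

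Fasn, the fatty acid synthase (chromosome 11, 120805846 to 120824547), was 4.08-fold lower in the cold, at 5957 ± 389 CPM in control and 1460 ± 604 CPM in cold mice (adjusted p = 0.0343). Cold mouse 15 had the lowest level. Without it the adjusted p was 7.26e-15, and it was 0.1, 0.083, 0.106, 0.0866 and 0.0979 without control mouse 2, cold mouse 4, control mouse 9, cold mouse 11 and control mouse 14. These were also the limits of its range over all alternatives. The remaining genes named in advance did not pass the test. Cidea, a lipid droplet protein of brown fat, had 2506 ± 95.2 and 2796 ± 164 CPM (adjusted p = 0.0945), although with a length offset or on flow cell 2 alone it was called (adjusted p = 0.042 and 0.0139, alternatives from 0.0139 to 0.379). Adrb3, the adrenergic receptor of fat cells, had 113 ± 16.2 and 99.4 ± 6.58 CPM (adjusted p = 0.296), and Prdm16, a regulator of brown fat identity, 23.4 ± 4.89 and 17.4 ± 1.83 CPM (adjusted p = 0.144). Adrb3 shares 481 nt with Gm45470 on the opposite strand, which had 119 reads against 1233, so its counts are uncertain to that extent.

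**Figure D2:**
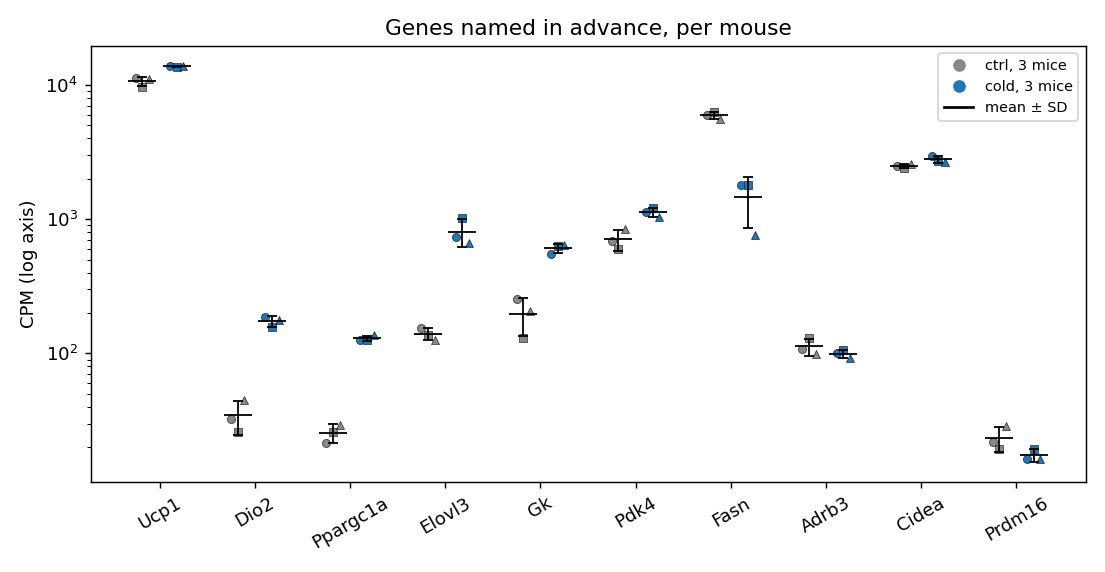
CPM on a log axis for the 10 genes named in advance, with 1 point per mouse (grey control, blue cold; 3 mice each) and bars for mean ± SD. Dio2, Ppargc1a, Elovl3 and Gk lie higher in all 3 cold mice than in any control mouse, Fasn lies lower, and Adrb3 overlaps between the groups.

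Beyond these, the 10 largest increases among abundant genes with non-overlapping groups began, after Ckb, with Gmpr. Gmpr, a guanosine monophosphate reductase (chromosome 13, 45507444 to 45553800), rose 18-fold to 2589 ± 289 CPM (n = 3, adjusted p = 0.000849). Slc25a34, a member of the mitochondrial carrier family, rose 11.7-fold (adjusted p = 4.63e-10), and Nnmt, which methylates nicotinamide, 11.3-fold, from 27.5 ± 1.19 to 313 ± 7.42 CPM (adjusted p = 4.36e-16). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose 8.5-fold (adjusted p = 0.00331), Atp1b1, a subunit of the sodium pump, 5.97-fold (adjusted p = 1.98e-11), and Cars2, a mitochondrial cysteinyl-tRNA synthetase, 5.3-fold (adjusted p = 2.02e-11). Adcy3, an adenylyl cyclase (chromosome 12, 4133103 to 4213525), rose 7.11-fold from 76.3 ± 22.3 to 540 ± 23.6 CPM (adjusted p = 5.23e-05). Cenpo, a centromere protein that lies on the opposite strand (chromosome 12, 4196004 to 4234294), was counted 6.46-fold higher. However, 99.7% of its reads fell on transcripts that overlap exons of Adcy3. Of its most-read transcript, 924 nt (21.3%) are shared with Adcy3. Whether the reads lie in that part was not examined, so the change of Cenpo is uncertain.

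Ntrk3, a neurotrophin receptor (chromosome 7, 78175959 to 78738012), showed the largest decrease under the same rule, 16.6-fold, from 86.5 ± 15.5 to 4.97 ± 4.16 CPM (n = 3, adjusted p = 0.000101). The size of this change depended on cold mouse 4, since the log2 fold change of -4.05 became -4.98 without it, in a range of -4.98 to -3.695 over all alternatives. Tmem45b was 5.77-fold lower (adjusted p = 6.95e-12), Car3, a carbonic anhydrase, 4.43-fold lower from 1973 ± 203 to 446 ± 48.6 CPM (adjusted p = 6.95e-12), and Immp2l, a peptidase of the mitochondrial inner membrane, 4.08-fold lower (adjusted p = 8.92e-10). Ttc25 was 5.52-fold lower (adjusted p = 0.0397), with an adjusted p of 0.07, 0.0737, 0.126 and 0.0663 without control mouse 2, cold mouse 4, cold mouse 11 and control mouse 14, and between 4.8e-07 and 0.132 over all alternatives. The other genes that fell most were enzymes and carriers of fatty acid synthesis.

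Of the 28 gene lists, 26 had enough tested members, and camera called 12 of them, 8 up and 4 down. With an estimated correlation between genes it called 0 lists, the lowest adjusted p being 0.327. Fry called 13 and its mixed test, which asks for change in either direction, 22. Neither fry test compares the members with other genes. As 19.5% of all tested genes were called, fry's calls do not show a change particular to these lists. Of the genes in the thermogenic programme, 11 of 25 tested members rose and 1 fell over all genes tested, and 14 rose and 1 fell adjusted over the list alone. The list's median log2 fold change was 0.33 (camera adjusted p = 0.00038; adjusted p = 0.36 with an estimated correlation). Bmp8b, a secreted growth factor of the list named for the size of its change, had 1 read in control and 59 reads in cold mice. The ratio was 62.2 with a counting interval of 10.8 to 2504. That 1 read came from control mouse 14, without which the fitted log2 fold change of Bmp8b went from 5.45 to 7.28. Early response genes to cAMP, the second messenger of adrenergic signals, were also higher as a list, with 8 of 24 members up and 0 down, 11 up adjusted over the list alone, and a median of 0.50 (camera adjusted p = 0.00144; adjusted p = 0.327 with an estimated correlation). Atf3, a stress-induced transcription factor, rose from 7 reads to 52, and Pde4d, a phosphodiesterase that breaks down cAMP, rose 1.89-fold (adjusted p = 0.000755), a call lost on flow cell 2 alone (adjusted p = 0.166; no alternative was higher).

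**Figure D3:**
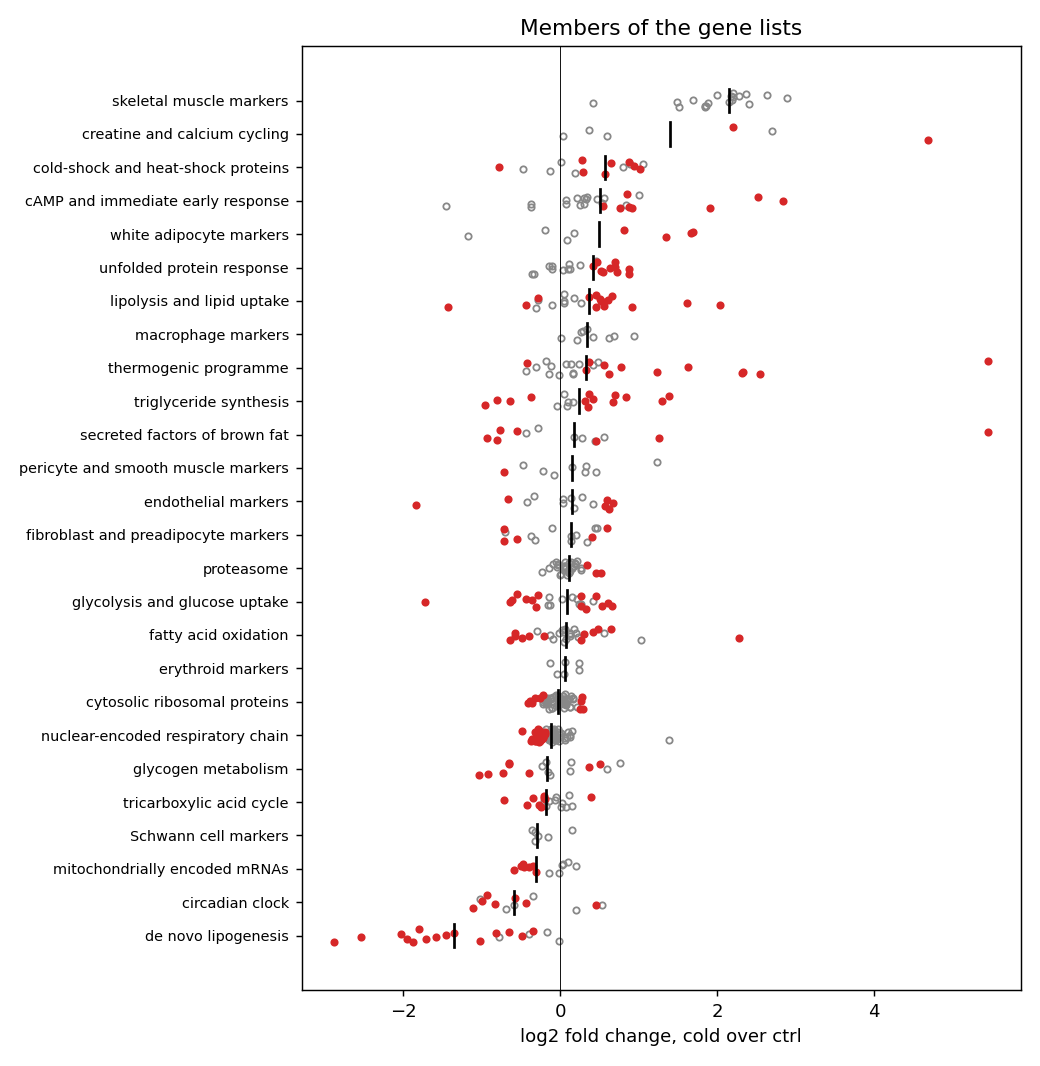
Log2 fold change in the cold of each tested member (points) of the 26 tested gene lists, filled red where the member was called, with a black bar at each list's median. The lists run from skeletal muscle markers, with a median of 2.15 and no called member, to de novo lipogenesis, with a median of -1.355 and 15 of 19 members lower.

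In de novo lipogenesis, 15 of 19 members fell and 0 rose, and the same 15 counted adjusted over the list alone, with a median log2 fold change of -1.355 (camera adjusted p = 4.61e-10; adjusted p = 0.36 with an estimated correlation). Acly (chromosome 11, 100476353 to 100528000) went from 2978 ± 827 to 404 ± 179 CPM (adjusted p = 0.0204), with an adjusted p of 0.0641, 0.0851 and 0.0708 without control mouse 9, cold mouse 11 and control mouse 14, in a range of 3.63e-09 to 0.0851 over all alternatives. Slc25a1, the mitochondrial citrate carrier, was 5.82-fold lower (adjusted p = 0.0123), and without cold mouse 11 its adjusted p was 0.0606, in a range of 7.63e-11 to 0.0606. Acaca was called under every alternative (adjusted p = 0.00806), and its near-identical copy Gm5182 had 50 reads against 7926. Scd1, which desaturates fatty acids, is outside this list's 4 named members but among the largest decreases, at 13550 ± 1790 and 3688 ± 1540 CPM (adjusted p = 0.0412), and only without cold mouse 15 did leaving out a mouse keep its call (adjusted p = 0.0226; 0.052 to 0.127 without each of the others, and 1.04e-05 to 0.158 over all alternatives).

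Genes that bring in, store and release lipid changed in both directions. Among lipolysis and lipid uptake genes 12 of 23 rose and 3 fell, as many adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.00394; adjusted p = 0.403 with an estimated correlation). Lpl, which frees fatty acids from circulating triglyceride, rose 3.07-fold from 2858 ± 636 to 8777 ± 367 CPM (adjusted p = 0.00462), and Fabp3, a fatty acid binding protein, 4.11-fold (adjusted p = 0.00643). Both lost the call in the fit on 4 libraries (adjusted p = 0.0951 and 0.0839, the highest of their alternatives). Fabp5, another binding protein, fell 2.69-fold (adjusted p = 0.000237). In triglyceride synthesis 9 of 18 members rose and 4 fell, as many adjusted over the list alone, with a median of 0.24 that camera did not call (adjusted p = 0.0532). Left without control mouse 2 or 14, or on either flow cell alone, this list was called (adjusted p = 0.0483, 0.0453, 0.0494 and 0.0343, in a range of 0.0249 to 0.548). Slc27a2, a fatty acid transporter, rose 2.61-fold (adjusted p = 0.00021) and Gpam, the first enzyme of glycerolipid synthesis, 1.79-fold (adjusted p = 4.64e-07). Fatty acid oxidation went both ways, with 6 of 29 members higher and 6 lower, 9 and 6 adjusted over the list alone, and a median of 0.08 (camera adjusted p = 0.523). Cpt1a, the entry enzyme of that pathway in many tissues, rose 4.84-fold from a low level of 6.04 ± 2.04 CPM (adjusted p = 9.88e-07), while Eci1, an enoyl-CoA isomerase, fell 1.55-fold (adjusted p = 3.57e-06).

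Carbohydrate pathways also moved in both directions. Of 24 glycolysis and glucose uptake genes 7 rose and 8 fell, 10 and 8 adjusted over the list alone, and the median of 0.09 and the mean of -0.04 had opposite signs, with the test direction up (camera adjusted p = 0.833). Pdk1 fell 3.29-fold (adjusted p = 0.00134) and Mpc1, part of the mitochondrial pyruvate carrier, 1.56-fold (adjusted p = 1.97e-06). In glycogen metabolism 2 of 16 members rose and 6 fell, as many adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.296), and Pygl, a glycogen phosphorylase, fell 2.05-fold (adjusted p = 0.000816). In the tricarboxylic acid cycle 1 of 19 rose and 8 fell, 1 and 10 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.112). There Pcx, the pyruvate carboxylase, fell 1.64-fold (adjusted p = 0.000566) and Idh3a rose 1.32-fold (adjusted p = 0.000145).

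Respiratory chain mRNAs were slightly lower. Of 69 nuclear-encoded subunits 25 fell and 0 rose, 26 fell adjusted over the list alone, and the median log2 fold change was -0.11 (camera adjusted p = 0.00173; adjusted p = 0.667 with an estimated correlation). Ndufa7 fell 1.4-fold and Uqcrq 1.28-fold (adjusted p = 0.000138 and 0.000481). Of 13 mitochondrially encoded mRNAs 7 fell and 0 rose, as many adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.0273; adjusted p = 0.667 with an estimated correlation). Without control mouse 2 or cold mouse 15 this list was not called (adjusted p = 0.183 and 0.0821, in a range of 0.00834 to 0.667). mt-Cytb, of complex III, fell 1.5-fold from 49740 ± 3710 to 33250 ± 734 CPM (adjusted p = 2.26e-07), and mt-Nd4 fell 1.38-fold (adjusted p = 2.8e-06). mt-Atp6 fell 1.42-fold, but a nuclear copy, Gm10925, matches 99.6% of its length and had 86115 reads against 487638, and mt-Nd4 and mt-Co2 share sequence with other nuclear copies, so the split of these reads is uncertain.

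Among creatine and calcium cycling genes 2 of 6 tested members rose and 0 fell, as many adjusted over the list alone, with a median of 1.40 (camera adjusted p = 0.00325; adjusted p = 0.36 with an estimated correlation). Besides Ckb (chromosome 12, 111669361 to 111672338, adjusted p = 0.000286), Alpl, an alkaline phosphatase, rose 4.61-fold from 9.58 ± 2.58 to 45.1 ± 6.13 CPM (adjusted p = 6.03e-08). Ckmt2, a mitochondrial creatine kinase outside the naming rule and picked after the values were seen, was not called and moved with the skeletal muscle markers within groups (correlation 0.986). The median rested on few genes, since leaving out Ckmt2, Ckb or Alpl gave 0.60 and leaving out any of the other members 2.20. With a skeletal muscle covariate the list kept its call (adjusted p = 0.00246). Genes of the unfolded protein response rose in 10 of 21 cases with 0 lower, or 11 higher and 1 lower adjusted over the list alone, with a median of 0.42 (camera adjusted p = 0.00325; adjusted p = 0.327 with an estimated correlation). Calr and Canx, chaperones of the endoplasmic reticulum, rose 1.83-fold and 1.66-fold (adjusted p = 8.87e-07 and 7.08e-06). Of the cold-shock and heat-shock proteins 7 of 15 rose and 1 fell, 9 and 1 adjusted over the list alone, with a median of 0.57 (camera adjusted p = 0.0089; adjusted p = 0.363 with an estimated correlation). The members that rose were heat-shock chaperones and partners, such as Hsp90aa1 at 2.02-fold (adjusted p = 0.0011) and Bag3 at 1.92-fold (adjusted p = 0.000134). Cirbp, a cold-induced RNA-binding protein, was 1.72-fold lower (adjusted p = 0.0133), with an adjusted p of 0.0519 and 0.0751 without control mouse 9 and cold mouse 15, and up to 0.189, by DESeq2, over all alternatives.

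Clock genes were lower as a list, with 1 of 13 higher and 6 lower, 2 and 8 adjusted over the list alone, and a median of -0.59 (camera adjusted p = 0.00394; adjusted p = 0.327 with an estimated correlation). Flow cell 2 alone did not call it (adjusted p = 0.075, in a range of 0.00385 to 0.327). Dbp, an output factor of the clock, fell 1.99-fold (adjusted p = 0.000324), where 541 nt overlap Sphk2 on the opposite strand, with 153 reads against 640. Secreted factors went both ways, with 3 of 13 higher and 4 lower, as many adjusted over the list alone, and a median of 0.17 (camera adjusted p = 0.833). Nrg4, a neuregulin, fell 1.91-fold (adjusted p = 1.6e-06), Vegfb fell 1.74-fold (adjusted p = 5.04e-06) and Cxcl14, a chemokine, rose 2.4-fold (adjusted p = 3.09e-05). Of 32 proteasome members 3 rose and 0 fell, 2 and 0 adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.0781). Of 57 cytosolic ribosomal proteins 4 rose and 6 fell, as many adjusted over the list alone, with a median of -0.03 (camera adjusted p = 0.523).

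Markers of other cell types were measured to see what else the tissue pieces held. Skeletal muscle markers had the highest list median, 2.15, but 0 of 19 members passed the test, over all genes or adjusted over the list alone, because the mice of each group differed widely (camera adjusted p = 0.00173; adjusted p = 0.667 with an estimated correlation of 0.968, and 0.35 by fry). The mean log2 CPM of the markers was 2.46, 4.11 and 4.68 in control mice 2, 9 and 14 and 3.53, 5.7 and 7.12 in cold mice 4, 11 and 15 (exact permutation p = 0.3). White adipocyte markers were higher, with 4 of 8 up and 0 down, as many adjusted over the list alone, and a median of 0.49 (camera adjusted p = 0.0273; adjusted p = 0.36 with an estimated correlation), a call lost on flow cell 1 alone (adjusted p = 0.0718, in a range of 0.0153 to 0.36). Npr3, the natriuretic peptide clearance receptor, rose 3.16-fold from 58.7 ± 13 to 187 ± 3.18 CPM (adjusted p = 2.54e-09), and Retn, the hormone resistin, 1.76-fold (adjusted p = 0.000237). Macrophage markers had a median of 0.34 with 0 of 9 members called, over all genes or adjusted over the list alone (camera adjusted p = 0.0514). Leaving out control mouse 2, cold mouse 4, control mouse 9 or cold mouse 11 gave adjusted p values of 0.015, 0.0235, 0.0144 and 0.0349 for that list, in a range of 0.0144 to 0.548.

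Camera called no list of the other cell types, while fry called the endothelial list (fry adjusted p = 0.0249). Of 14 endothelial markers 4 rose and 2 fell, 5 and 2 adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.337), and Rgcc rose 1.59-fold (adjusted p = 1.7e-06). Of 15 fibroblast and preadipocyte markers 2 rose and 3 fell, 4 and 4 adjusted over the list alone, and the median of 0.13 had the opposite sign to the mean of -0.05 and to the test (camera adjusted p = 0.833). There the collagen gene Col3a1 fell 1.64-fold (adjusted p = 0.000282) and Ly6a rose 1.51-fold (adjusted p = 0.000471). Of 9 pericyte and smooth muscle markers 0 rose and 1 fell, 1 and 2 adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.833), and Rgs5 fell 1.64-fold (adjusted p = 4.59e-05). Schwann cell and erythroid markers had 6 tested members each, 0 of them called over all genes or adjusted over the list alone, with medians of -0.30 and 0.06 (camera adjusted p = 0.523 and 0.833). Cell division and lymphocyte lists had 1 tested member each, Pcna at 15.3 ± 1.73 and 13.5 ± 3.79 CPM and Ighm at 9.79 ± 4.27 and 8.71 ± 2.31 CPM, and were not tested. As mean log2 CPM over all members with reads, lymphocyte markers were 1.17 ± 0.105 in control and 0.81 ± 0.111 in cold mice, and macrophage markers 2.34 ± 0.204 and 2.66 ± 0.152 (exact permutation p = 0.1 each, 0.2 adjusted).

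The counts were given per transcript, so the comparison was repeated for transcripts. Of 11699 tested transcripts 975 were higher and 930 lower (16.3%), of which 324 and 278 changed more than 2-fold. The groups did not overlap in 3767 transcripts (32.2%), against 10% by chance. DESeq2 called 483 higher and 398 lower transcripts, and flow cell 2 alone gave 466 and 446. Among the changed transcripts 141 belonged to genes that were not called, and 3 genes had both a higher and a lower transcript, namely 1700037H04Rik, Tspan18 and Rps24.

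Transcript usage, the share of a gene's reads that each of its transcripts takes, was called as changed in few genes. The test recovered 23.6% of simulated 2-fold changes, so many changes of that size can have been missed. Starts and ends given below are those of the annotated transcripts, and where the reads began or ended was not examined. The clearest case was Rps24, a protein of the small ribosomal subunit (chromosome 14, 24487125 to 24496959), where the transcript Rps24-210 took 8.49% ± 0.68 of reads in control and 22% ± 3.1 in cold mice (SD, n = 3; adjusted p = 9.19e-09). This transcript ends at 24496959, past the ends, between 24495432 and 24495858, of the gene's other transcripts with at least 20 reads. Of its 1613 nt, 1101 are in none of those transcripts. Rps24-205 went from 60.9% ± 1.06 to 46.5% ± 3.64 of reads, a shift in usage that was not called for that transcript itself (adjusted p = 0.371), while the whole gene fell 1.28-fold (adjusted p = 0.00186). In 1700037H04Rik (chromosome 2, 131146324 to 131160081), a gene not called as a whole (adjusted p = 0.62), the retained-intron transcript 1700037H04Rik-204 starting at 131149028 rose from 28.5% ± 2.89 to 58.5% ± 1.34 and 1700037H04Rik-207 fell from 60.9% ± 1.73 to 34% ± 0.85 (usage adjusted p = 2.04e-06). In Tspan18, a membrane tetraspanin (chromosome 2, 93201760 to 93334505), the short transcript Tspan18-205 starting at 93312515 rose from 10.4% ± 0.6 to 49.2% ± 7.04 and the protein-coding Tspan18-202 went from 58.1% ± 1.06 to 31.1% ± 6.22 (usage adjusted p = 4.33e-05 for the gene and 3.78e-05 and 0.093 for these transcripts, so that of Tspan18-202 was not called).

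The other genes called for usage were Ergic1 and Eci2. In Ergic1 (chromosome 17, 26561489 to 26656934) the retained-intron transcript Ergic1-204 rose from 3.48% ± 1.7 to 19.7% ± 0.89 (usage adjusted p = 0.00146), and without control mouse 14 or on flow cell 2 alone the call was lost (adjusted p = 0.06 and 0.0611, in a range from 0.00096). In Eci2 (chromosome 13, 34977748 to 35027096) the transcript Eci2-214 rose from 1.3% ± 0.34 to 5.32% ± 0.67 (usage adjusted p = 0.0022). Eci2-214 shares no exon sequence with the gene's other transcripts of at least 20 reads. Its call was lost without control mouse 2 and cold mouse 4 (adjusted p = 0.0645 and 0.0545), on flow cell 1 alone and by limma voom (0.0829 and 0.0672), and the lowest alternative was 0.00489. These were the 5 genes called among 2568 tested. At an unadjusted p under 0.05 there were 78 genes, fewer than the 128.4 expected at that threshold for evenly spread p-values. The F test per gene called 17 genes, the 5 among them, limma voom called 13, of which 4 were shared, and flow cell 2 alone called 3. Of the genes chosen in advance, Ppargc1a, Gk, Lpin1, Acaca and Pkm were tested and none passed (usage adjusted p = 0.547 for Ppargc1a and 1 for the others). Ppargc1a-204, which is annotated to start at 51567704, upstream of the main start, took 0.9% ± 1.56 of reads in control and 6.1% ± 1.28 in cold mice.

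**Figure D4:**
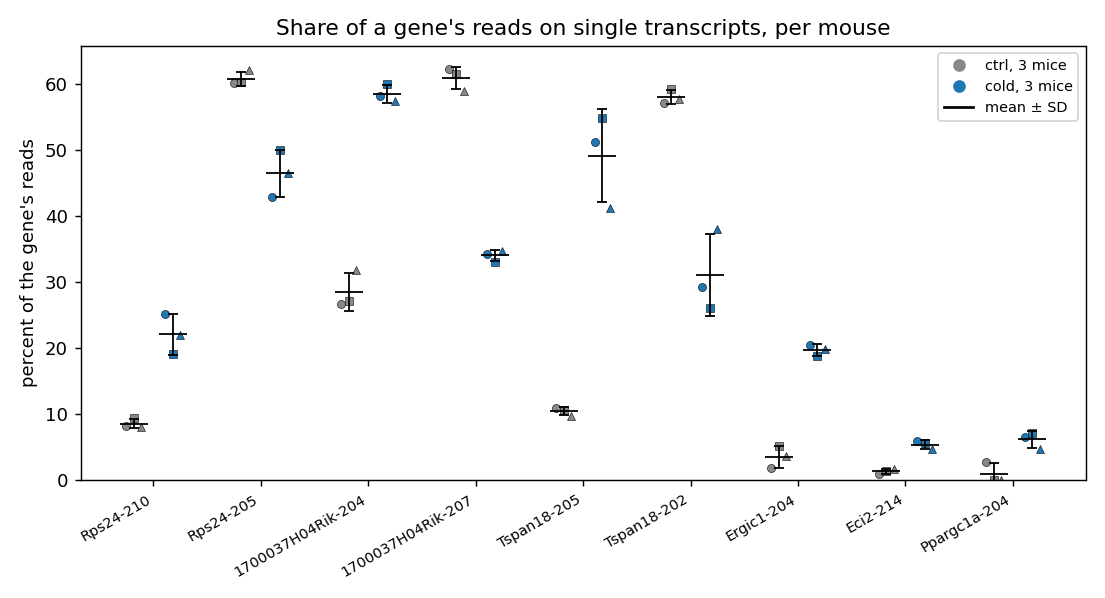
Percent of a gene's reads on single transcripts in each mouse (grey control, blue cold; 3 mice each), with bars for mean ± SD. Rps24-210 rises from 8.49% to 22% and 1700037H04Rik-204 from 28.5% to 58.5%, while Ppargc1a-204, which did not pass the test, stays below 10%.

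Mitochondrial RNA took a smaller share of reads in the cold, and its makeup differed. Mitochondrial mRNA made up 29.3% ± 0.955 of reads in control and 23.9% ± 0.913 in cold mice (SD, n = 3), and mitochondrial rRNA, which is not the target of poly(A) capture, 1.61% ± 0.529 and 4.21% ± 0.573. Each of these, with mitochondrial tRNA at 0.126% ± 0.0355 and 0.222% ± 0.071, separated all cold from all control mice, with an exact permutation p of 0.1, the smallest that 3 against 3 mice can give (0.2 adjusted over 20 measures). The 10 most abundant genes held 30.3% ± 0.861 of reads in control and 27.2% ± 0.586 in cold mice (exact permutation p = 0.1). The read-weighted mean transcript length was 1941 ± 33.7 nt and 2002 ± 23.4 nt (exact permutation p = 0.1), and without mitochondrial genes 2361 ± 21 and 2377 ± 28.9 nt (exact permutation p = 0.5). Transcripts annotated for nonsense-mediated decay held 2.88% ± 0.0378 of nuclear reads in control and 2.74% ± 0.0209 in cold mice (exact permutation p = 0.1). After thinning to 1657985 reads, 15550 ± 158 and 15590 ± 175 genes were detected (exact permutation p = 0.8).

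**Figure D5:**
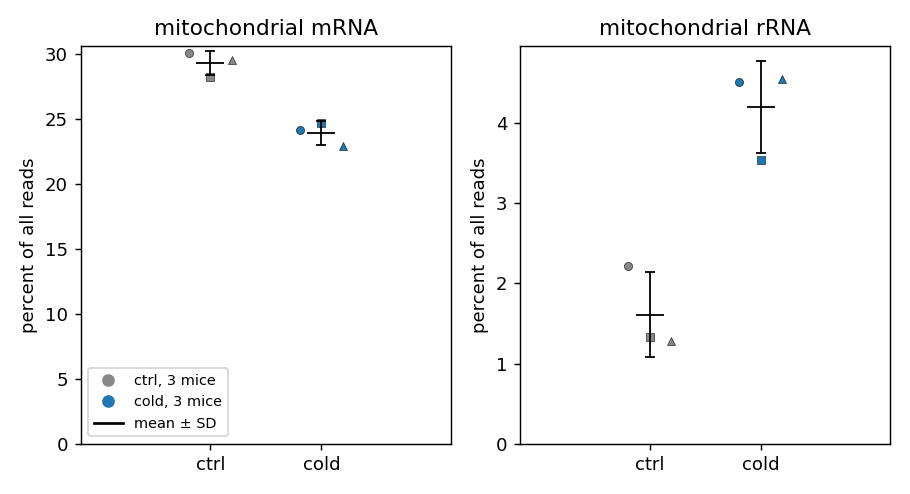
Percent of all reads on mitochondrial mRNA (left) and mitochondrial rRNA (right) in each mouse (grey control, blue cold; 3 mice each), with bars for mean ± SD and axes from 0. The mRNA share is lower in all 3 cold mice, at 22.9 to 24.7% against 28.2 to 30.1%, and the rRNA share higher, at 3.54 to 4.55% against 1.29 to 2.22%.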

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

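In this part the tests of mitochondrial RNA, of Cenpo against Adcy3 and of the correlation among muscle markers were chosen only after the result was seen. Reads on transcripts outside the annotation release were left out of the gene, transcript, usage and list tests. They made up 0.0935% ± 0.0057 (SD, n = 3) of reads in the cold and 0.0748% ± 0.0072 in control mice, with every cold mouse above every control mouse (exact permutation p = 0.1, the smallest possible).

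Mitochondrial rRNA was higher and mitochondrial mRNA lower in the cold, by 1.42 ± 0.28 and -0.29 ± 0.04 (SE over mice) as log2 ratios of read shares. Of the 2 tested mitochondrial rRNA genes, 1 was called higher and 1 was not called. Library scaling cannot account for this opposite shift of rRNA and mRNA. The ratio of rRNA to mRNA reads within each library, which no scaling moves, was higher by 1.71 ± 0.28 with no overlap of the groups. A general carry-over of RNA without a poly(A) tail would raise nuclear-encoded rRNA and small RNA alike, but their share changed by 0.07 ± 0.11. They held only 2375 reads over all libraries, 1750 of them from 1 gene. Carry-over of RNA that these few reads do not reflect is therefore not excluded. Reads lost to 9 nuclear copies of mitochondrial sequence do not account for the mRNA part, which stayed at -0.28 ± 0.04 with the copies added in. A change of mitochondrial RNA or of its adenylation in cold brown fat may lie behind it, as may a shift in how rRNA was captured, and both remain untested.

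Cenpo, which lies on the opposite strand to Adcy3, was counted 6.46-fold higher in the cold. Its reads on transcripts that overlap exons of Adcy3 went from 88 to 578 and those of Adcy3 from 442 to 3132, and its single transcript without overlap had 2 reads and 0 reads. The log2 ratio of Cenpo to Adcy3 reads differed between the groups by -0.16, less than the pooled SD of 0.28 between mice, which is consistent with reads of Adcy3 counted for Cenpo. Over 383 pairs of genes with overlapping exons on opposite strands, fold changes also correlated more than over 1475 neighbouring pairs, with a difference in rho of 0.173 (95% bootstrap interval 0.059 to 0.283), and 15 of 16 overlapping pairs in which both genes were called moved the same way, against 33 of 53. Cenpo and Adcy3 are themselves among these overlapping pairs. A real response of Cenpo, or regulation shared by overlapping genes, remains open.

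Skeletal muscle markers varied between mice of both groups and were higher on average in the cold. After removing the group means, the 19 markers varied together, with a median pairwise correlation of 0.978, as muscle carried over at dissection would make them do, but not in a fixed ratio. Acta1 and Myl1 lie outside the naming rule and were picked for their level after the values were seen. Acta1 stood at 11.6, 72 and 120.5 CPM in control mice 2, 9 and 14. In cold mice 4, 11 and 15 it stood at 43.5, 236.4 and 666.1 CPM. Myl1, at 84.5 to 274.2 CPM, varied least of the abundant markers. Of the 847 genes called higher, 18.3% ranked the cold mice as muscle does, against 1 in 6 by chance. This share cannot decide whether muscle carry-over contributed to these calls. Genes that follow muscle vary widely within groups, and 0 of the 19 markers were called, so a high share was unlikely among called genes. With a skeletal muscle covariate 616 genes were higher. A joint change of muscle genes within the depot would also make them vary together and remains untested.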

How the results depend on the processing

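In this part the skeletal muscle covariate, the fit on 4 libraries and the comparison of spread estimates between DESeq2 and edgeR were chosen only after the result was seen. No paired analysis was possible because the groups share no mouse number. RLE size factors, limma voom, both filters, mitochondrial genes left out, the length offset and the legacy fit left each count of genes or transcripts they were run on within 1.5 times, and no setting moved the median of all genes by more than 0.1 on the log2 scale. No called gene or transcript shared between a setting and the reported fit changed direction. DESeq2 called 467 higher and 353 lower genes and 483 higher and 398 lower transcripts, 776 of the genes and 845 of the transcripts shared. Its fold changes correlated at 0.9997 with those of edgeR. Its median dispersion was 0.138, against 0.0104 for edgeR's tagwise estimate, under 100 reads (42 against 158 calls). At 300 to 1000 reads these were 0.0247 and 0.00729 (265 against 618 calls). The quasi-likelihood test does not take its spread from the tagwise estimate, so these values alone do not explain the difference in calls. Flow cell 2 alone gave 429 higher and 408 lower genes, 466 higher and 446 lower transcripts and 3 usage genes, from fewer tested genes (5348). Usage calls rose to 17 with an F test and 13 with limma voom; the cause was not tested. The skeletal muscle covariate left 616 higher and 561 lower genes and the fit on 4 libraries 569 and 506, the latter with fewer samples; for the former the cause was not tested. The skeletal muscle markers, as a list, turned downward with adjusted p = 0.941 under that covariate, by construction (range 3.29e-10 to 0.941). With 1 mouse left out, 669 to 737 genes were higher and 644 to 684 lower, 724 to 831 transcripts higher and 707 to 776 lower, 4 to 6 genes changed usage and 11 to 13 lists were called.

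Camera with an estimated correlation called 0 lists, against 13 by fry. Fry does not compare members with other genes, so its calls answer another question than camera's. With the estimated correlation left aside, the thermogenic, cAMP, lipogenesis, lipolysis, nuclear respiratory chain, creatine, unfolded protein and heat-shock lists kept their call in every alternative. Mitochondrial mRNAs lost theirs by fry and with the covariate (adjusted p = 0.0606 and 0.253). The triglyceride synthesis, proteasome and endothelial lists gained one by fry (0.0249 each), and triglyceride synthesis also with the covariate (0.0456). Of the named genes' values under alternatives, 1790 stayed on their side of the threshold, 144 lost the call, 7 gained it and 0 reversed. Counting limits genes of low level: 3 reads are 1.34 to 1.81 CPM, and 23.6% of simulated 2-fold usage changes were recovered.

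Of the 10 ways to split the 6 libraries 3 against 3, only 1, the real one, gave as many calls as it did for genes (1695, highest other 0), transcripts (1905, highest other 0), usage (5, highest other 0) and lists (12, highest other 6). So few splits cannot give a share under 0.05. Every other split puts cold and control mice on both sides, which adds their difference to the spread within a side. The 0 calls of genes, transcripts and usage there therefore say little about chance. With 0 genes called, these splits still called 3 to 6 lists.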

Other observations

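The gene families and the pooling by start site in this part were chosen only after the data were seen, as were Tuba1c, Tkt, Taldo1, Gstp1 and Sc5d, which lie outside the naming rule. Of 32 families looked at, 31 had enough tested members and camera called 7, but with an estimated correlation it called 0 (adjusted p = 0.467 for each of the 7). Tubulins rose in 4 of 9 cases, led by Tuba1c with a log2 fold change of 1.56 ± 0.18 (SE, adjusted p = 1.74e-06), although tubulin genes resemble each other in sequence and their shared reads were not examined (camera adjusted p = 0.0102).

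The pentose phosphate pathway, which supplies reducing power for fatty acid synthesis, fell in 5 of 7 cases (camera adjusted p = 0.0102), with Tkt from 2403 ± 220 to 801 ± 133 CPM (n = 3, adjusted p = 4.59e-05) and Taldo1 from 1459 ± 98.6 to 677 ± 66.1 CPM (adjusted p = 9.47e-10). Glutathione S-transferases, which conjugate reactive compounds, fell in 6 of 14 cases, among them Gstp1 from 192 ± 19.3 to 121 ± 7.19 CPM (adjusted p = 3.7e-05; camera adjusted p = 0.0102). Genes of cholesterol synthesis and uptake fell in 7 of 21 cases and rose in 2, with Sc5d from 92.7 ± 17 to 49.4 ± 5.18 CPM (adjusted p = 4.36e-05). Genes taken as MHC genes by symbol alone, not all of which need be such, fell in 4 of 12 cases and rose in 1. Many of them also resemble each other in sequence. Small nucleolar RNA host genes fell in 3 of 9 cases. Camera gave an adjusted p of 0.028 for each of these last 3 families.

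The hypothesis that pooling transcripts by start site shows usage changes that single transcripts miss was tested. Among 1016 genes with several annotated start sites 4 were called, and 29 had an unadjusted p under 0.05, where 50.8 are expected for evenly spread p-values. The 4 genes, 1700037H04Rik, Ergic1, Eci2 and Tspan18, were also called with single transcripts, so pooling called no gene that single transcripts had missed. Ppargc1a was not called (adjusted p = 0.281). Its 2 transcripts annotated to start between 51567704 and 51567726 had 1, 0 and 1 reads in the control mice and 25, 21 and 15 in the cold mice. Their share was 1.43% ± 1.36 against 8.09% ± 1.59 (exact permutation p = 0.1, the smallest possible). Where the reads themselves began was not examined.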
